A study of Physcomitrium patens with 47 samples.

How the data were processed

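Messenger RNA of the moss Physcomitrium patens was measured in 47 libraries by 3′ tag sequencing, in which each read comes from the 3′ end of a transcript, so that a gene's count does not depend on its length. The plants were wild type (WT), lines in which the gene COX11 had been disrupted and lines in which the gene NDUFA5 had been disrupted. Per the labels' protocols, a mixture of protonema (the filamentous juvenile stage) and young gametophores (the leafy shoots) was grown over liquid medium in closed boxes, in days of 12 h light and 12 h dark. RNA was taken at zeitgeber time (ZT, hours after lights on) 0, 2 or 6. The ZT0 boxes had been wrapped in foil since ZT12 and the plants were frozen in dim green light, whereas the ZT2 and ZT6 plants were frozen in the lit chamber.

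The authors deposited 1 table of estimated counts per gene for the whole series, with no normalization. Bowtie2 2.2.5, SAMtools 1.6 and HTSeq 2.0.2 are named in the submitters' processing notes, with no parameters. The genome build and annotation are not given in the sources used here. The deposited estimated counts were not all whole numbers: 2.35% of the values lay more than 1e-06 from a whole number, in 2085 of the 32926 genes. How these fractions arose is not given in the sources used here, and the values of the 1423 tested genes with such counts are uncertain to that extent. The design had been written for raw counts. The estimated counts were rounded to whole numbers, which the same test accepts. The table has 57 columns of values, of which 47 carry the sample code of a library of the series and 10 match no sample used here. Those 10 were not used. The 5 summary lines of HTSeq, which name no gene, were left out of library sizes and tests. They held between 26.2% and 39.9% of a library's counts, these lines included. As parts of the same whole, 10.9% to 22.4% were reads not aligned and 12.2% to 16.6% alignments of low quality. Reads in no gene were 0.619% to 1.19% and ambiguous reads 1.13% to 1.60%.

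Group, line and replicate were taken from the sample titles. For 1 NDUFA5 KO library at ZT6 (46-3), the title gives line 46 and the characteristics give line 48. The title was followed, and the other reading was tried. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may in part be technical. Over the 105 pairs of libraries within groups, chi-square per gene (genes with at least 20 counts in the pair) lay between 2.44 and 69.4, above the value of 1 that sampling alone gives, so no library was treated as a copy of another. Pairs within a group were uneven. At ZT0, COX11 KO 150-3 and 152-2, of different lines, had 2.80, whereas 152-1 and 152-2, of the same line, had 17.45. The tests treat all libraries of a group as independent, and libraries that share a culture or handling would make the p-values too small. The sample codes begin with A or Z. What the letter stands for is not stated, and it was tried as a covariate.

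Differential expression was tested with edgeR 4.0.16 under R 4.3.3 (limma 3.58.1 underneath). Genes were kept by filterByExpr over the 9 groups of genotype and time, which left 18460 genes. Libraries were scaled by TMM. A negative binomial model with 1 mean for each of the 9 groups was fitted to all 47 libraries, and contrasts were tested with the quasi-likelihood F test at a Benjamini-Hochberg false discovery rate (FDR) of 0.05 within each contrast. The common biological coefficient of variation was 21.8%. The contrasts were each knockout against WT at each time, the knockouts against each other at each time, the WT times against each other, and the difference of each knockout effect between ZT2 or ZT6 and ZT0. The lines of each genotype were compared in a model with 1 mean for each line and time, averaging the times. These tests, their samples and the rule for named genes were fixed before the data were examined. Standard errors of log2 fold changes were derived from the F statistic. Values per library are CPM, with library totals scaled by TMM, and log2 CPM uses a prior count of 2.

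The rule for named genes took, in each contrast, genes at FDR 0.05 with average log2 CPM above 1 and, between groups, every library of the first group on the same side of the mean of the other, ranked by log2 fold change. Because the gene identifiers (IDs) are not paired with gene names in the files or in the reference, where 0 of the IDs were found, the rule allows 2 IDs per direction. For the same reason the planned tests of gene lists (camera and fry) and the check of the targeted genes COX11 and NDUFA5 could not be run. A fold against a group with 0 counts in every library is given as a lower bound, computed against a floor of 3 counts over that group. Where a group held 1 to 3 counts, the ratio is given with an exact 95% binomial interval. Intervals and floors cover counting error only. Groups of 4 to 10 libraries were searched for a library far from the rest with Dixon's ratio. Groups at 0 in every library, or spanning less than 0.01, were skipped, a limit set after the first results had been seen. Counts of called genes were compared with those of 30 splits of the libraries of each contrast.

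Effects of the knockouts were compared by the correlation and covariance of their log2 fold changes over genes and by counts of genes called in the same direction. These were repeated with separate WT libraries for each knockout. Unchanged knockouts were also simulated around the observed WT means (10 simulations). Other analyses were chosen after the data had been examined. These are the comparison of genes by the prefix of their ID (the part before the _ sign), genes whose values in one genotype do not overlap those in the others, and the change from ZT0 to ZT2 of genes chosen in part of the WT libraries. For the first, the median over the genes of an ID prefix of log2 CPM minus the mean of the other WT libraries of the same time was taken in each library. Genotypes were compared over 27 prefixes by 2-sided permutation tests with 100000 resamples, adjusted over 54 tests. In the last, every choice of part of the WT libraries at ZT0 and ZT2 was used (120 choices), and the change was measured in the remaining WT libraries and in the knockouts.

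The functions were tested on simulated counts with the means, dispersions and library sizes of the real genes. For COX11 KO against WT at ZT0, with 18070 genes, the test recovered 96.9% of genes changed 4-fold, 64.1% of those changed 2-fold and 30.3% of those changed 1.5-fold, and called 5 of 16929 unchanged genes. For the difference of the NDUFA5 KO effect between ZT2 and ZT0 it recovered 78.5%, 28.4% and 4.62%. For line 150 against line 152 it recovered 92.4%, 75.8% and 44.8%. Few genes were changed in each simulated contrast and libraries were drawn independently, whereas many genes were called in most real contrasts. The shares of recovered and false calls need not hold there. A simulated doubling of 768 genes sharing a prefix gave a median of 0.97, with the other prefixes between -0.020 and 0.0079.

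The alternatives tried were RLE factors, library totals only, DESeq2 1.42.0, no filter, a stricter filter (at least 10 counts in at least 10 libraries), the code letter as covariate or only 1 letter, the number in the title as a block, only the compared groups, the mean of both lines, both readings of the conflicting label, each library left out in turn, and sets of genes or libraries left out after the data had been examined.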

Results

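The series asks how respiration shapes the metabolism of Physcomitrium patens, a moss whose dominant stage is haploid. COX11 is an assembly factor of cytochrome c oxidase, the respiratory complex IV, and NDUFA5 is a subunit of NADH dehydrogenase, the respiratory complex I. A segment of either gene had been disrupted by a resistance cassette in 2 lines each, 150 and 152 for COX11 KO and 46 and 48 for NDUFA5 KO. Transcripts were counted at the end of the night (ZT0), and 2 h and 6 h into the light (ZT2 and ZT6). WT had 6, 4 and 8 libraries at these times, COX11 KO had 5 at each, and NDUFA5 KO had 4, 5 and 5. Counts in genes ranged from 4060158 to 10349604 per library, with a median of 5659267. The second highest total was 6714980. Genes are given by the identifiers of the deposited table, which are not paired with gene names there. The targeted genes were therefore not checked by name, and gene groups are not described by function.

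Time of day and genotype both separated the libraries. The first principal component of log2 CPM held 28.3% of the variance and set ZT0 libraries apart from those in the light. Its scores at ZT0 were 45.5 ± 19 in WT (SD, n = 6), 45.3 ± 11.8 in COX11 KO (n = 5) and 138 ± 6.23 in NDUFA5 KO (n = 4). They were uneven within groups. WT libraries 1, 2 and 3 and COX11 KO 152-1 lay between 25.3 and 31.5, and the other WT and COX11 KO libraries at ZT0 between 46.0 and 64.9. The former carry lower sample code numbers than the latter. These numbers were not tried as a covariate. The second component held 23.5%, and its scores were lower in WT than in either knockout at each time. In WT they were -79.8 ± 14.6 at ZT0, -27.5 ± 6.38 at ZT2 (n = 4) and -52.9 ± 12.2 at ZT6 (n = 8). In COX11 KO they were 3.6 ± 5.99, 56.7 ± 5.67 and 22.5 ± 6.53 (n = 5 each), and in NDUFA5 KO 25.7 ± 6.86, 69.8 ± 24.1 and 29.3 ± 13.2.

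**Figure D1:**
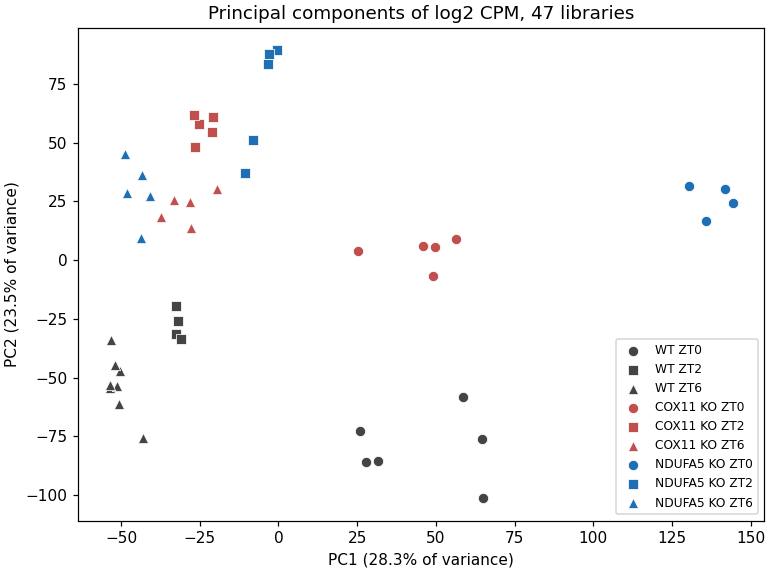
Scores of the 47 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, with colour for genotype and symbol for time. The 4 NDUFA5 KO libraries at ZT0 lie at 138 ± 6.23 on the first component, apart from WT and COX11 KO at the same time.

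At the end of the night, COX11 KO differed from WT in 7488 of 18460 genes, of which 3667 were higher and 3821 lower, and 2776 changed at least 2-fold. Pp3c25_14630 was the more abundant of the named genes that rose, with 165 ± 40.1 CPM (SD, n = 5) against 2.94 ± 0.886 in WT (n = 6), a log2 fold change of 5.78 with a standard error of 0.752. Pp3c21_13440 had 4.06 ± 1.73 CPM in COX11 KO and 0 counts in all 6 WT libraries, and was at least 38-fold higher. Pp3c11_18420 and Pp3c12_14210 had 0 counts in all 5 COX11 KO libraries. They were at least 466-fold and at least 399-fold lower than in WT as a group, where they varied widely (51.7 ± 44.7 and 44.1 ± 69.8 CPM). WT libraries held 4 to 630 counts of Pp3c11_18420 and 0 to 874 of Pp3c12_14210, with 1 of the 6 at 0 for the latter.

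In the light, COX11 KO differed from WT in 5516 genes at ZT2 (2526 higher, 2990 lower, 2342 at least 2-fold) and 8088 at ZT6 (3827 higher, 4261 lower, 2750 at least 2-fold). At ZT2, Pp3c21_13440 reached 5.05 ± 1.08 CPM (n = 5) against 1 count over the 4 WT libraries, a ratio of 114 (95% counting interval 20.2 to 4530). Pp3c4_23050 reached 6.83 ± 1.56 CPM against 3 counts in WT, a ratio of 50.9 (17.2 to 248). Pp3c1_34890 (15.6 ± 9.7 CPM in WT, n = 4) and Pp3c5_3169 (13.5 ± 17.2) had 0 counts in COX11 KO, at least 167-fold and at least 146-fold lower. At ZT6, Pp3c7_12530 reached 5.11 ± 2.55 CPM (n = 5) against 3 counts over 8 WT libraries, a ratio of 66 (22.1 to 324), and Pp3c21_13440 reached 3.74 ± 1.04 against 0.0985 ± 0.106 CPM. Pp3c11_18420 (27.6 ± 28.7 CPM in WT, n = 8) and Pp3c10_18650 (24.2 ± 16.3) each had 1 count in COX11 KO, ratios of WT to knockout of 828 (148 to 32700) and 738 (132 to 29200). For the named genes of the COX11 KO contrasts, adjusted p in edgeR's quasi-likelihood test lay between 1.67e-12 and 3.5e-05.

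The share of higher genes depended on the scaling. With library totals only, in place of TMM, 73% of the genes called in COX11 KO were higher at ZT0 (49% with TMM), 68.5% at ZT2 (45.8%) and 71.5% at ZT6 (47.3%). That scaling moved the median log2 fold change of all genes to 0.21, 0.18 and 0.19. Genes of the ID prefix Pp3c2 (the part of the ID before the _ sign), 6.19% of the genes tested, made up 24.7%, 34% and 22.5% of the genes called higher with TMM at the 3 times.

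NDUFA5 KO at the end of the night differed from WT in 11380 genes, 61.6% of those tested, with 5541 higher and 5839 lower and 5883 changed at least 2-fold. Pp3c12_25330 had 193 ± 35.1 CPM (n = 4) against 0.749 ± 0.516 in WT (n = 6), a log2 fold change of 7.95 with a standard error of 0.352. Pp3c24_12720 had 37.7 ± 8.83 CPM against 1 count in WT, a ratio of 1110 (199 to 44100). Pp3c5_12950 was lower, with 0.673 ± 0.465 CPM against 566 ± 655 in WT, a log2 fold change of -9.85 with a standard error of 1.07. Pp3c16_3130 (27 ± 17.7 CPM in WT, 3 to 250 counts per library) had 0 counts in the 4 knockout libraries, at least 201-fold lower.

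NDUFA5 KO differed from WT in 8113 genes at ZT2 (4220 higher, 3893 lower, 3371 at least 2-fold) and 7244 at ZT6 (3455 higher, 3789 lower, 2366 at least 2-fold). At ZT2, Pp3c9_23030 had 25.5 ± 26.7 CPM (n = 5) against 0.2 ± 0.294 in WT (n = 4), and Pp3c4_23050 had 16.2 ± 13.1 CPM against 3 counts in WT, a ratio of 118 (40 to 572). Pp3c11_18420 (77.8 ± 81 CPM in WT) had 1 count in NDUFA5 KO, a ratio of WT to knockout of 2250 (403 to 88900), and Pp3c14_20550 (10.3 ± 10.3 in WT) had 0, at least 99.6-fold lower. At ZT6, Pp3c11_12000 had 19 ± 10 CPM (n = 5) against 0.299 ± 0.371 in WT (n = 8), and Pp3c7_12530 had 7.12 ± 0.949 CPM, a ratio of 94.7 (32 to 463). Pp3c22_10770 (14.2 ± 9.32 CPM in WT) had 0 counts in NDUFA5 KO, at least 141-fold lower, and Pp3c1_34890 (18.7 ± 24.7) had 1, a ratio of 564 (101 to 22300). For the named genes of the NDUFA5 KO contrasts, adjusted p in edgeR's quasi-likelihood test lay between 1.21e-22 and 1.47e-05.

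With library totals only, 37.8% of the genes called in NDUFA5 KO were higher at ZT0 (48.7% with TMM) and 71% at ZT6 (47.7%), and the median log2 fold change of all genes moved to -0.23 at ZT0, 0.11 at ZT2 and 0.165 at ZT6. Within libraries of code letter Z, 7380 and 7222 genes were called for COX11 KO and 10897 and 6049 for NDUFA5 KO at ZT0 and ZT6. Within letter A, 6743 and 6950 were called at ZT2, where the only NDUFA5 KO libraries with that letter are the 2 of line 48.

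**Figure D2:**
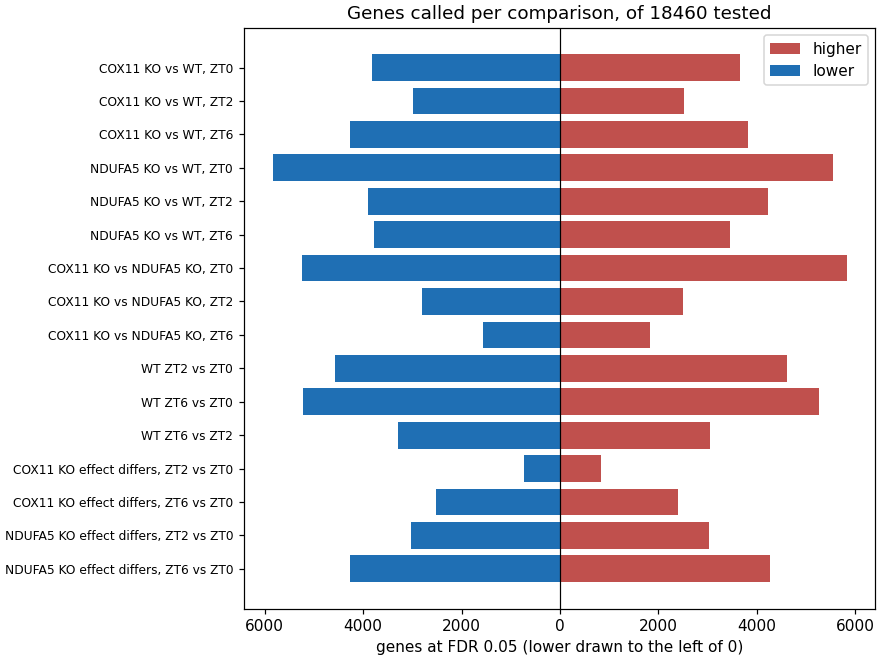
Number of genes called at FDR 0.05 per contrast (x axis, higher to the right of 0 and lower to the left), of 18460 tested. NDUFA5 KO against WT at ZT0 has 5541 higher and 5839 lower genes, against 3667 and 3821 for COX11 KO at the same time.

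Effects of the knockouts ran in the same direction over many genes at each time. The correlation of their log2 fold changes across genes, which are not independent replicates, was 0.607 at ZT0, 0.743 at ZT2 and 0.779 at ZT6. With separate WT libraries for each knockout the correlation was 0.547 and 0.534 at ZT0, 0.668 and 0.664 at ZT2, and 0.725 and 0.723 at ZT6. The covariance was 0.968, 0.82 and 0.701 at the 3 times. With separate WT libraries it was 0.918 and 0.878, 0.785 and 0.784, and 0.67 and 0.673. Unchanged knockouts simulated around the observed WT means gave correlations of 0.0223, 0.0171 and 0.0193 and covariances of at most 0.00143. Values near 0 were built into that simulation, which leaves out the error of the shared WT libraries. At ZT0, 1755 genes were higher and 2006 lower in both knockouts, where independent lists would share 1101 and 1209, and 1226 were called in opposite directions. At ZT2, 1667 were higher and 2161 lower in both (577 and 631 for independent lists), with 118 opposite. At ZT6, 2268 and 2517 were shared (716 and 875), with 104 opposite. Without the genes of the ID prefixes Pp3c2, Pp3c25 and Pp3c27, the genes higher in both fell to 1073, 1019 and 1445 at the 3 times (746, 321 and 430 for independent lists), and 1919, 2092 and 2410 were lower in both. With separate WT libraries at ZT2, 925 and 924 were higher and 1406 and 1360 lower in both. All knockout libraries carry a shift of Pp3c2 genes that no WT library has (below). Differences from WT that both knockouts share can therefore not be told apart from anything else the knockout lines share. Leaving those genes out does not remove effects on other genes.

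The knockouts themselves differed most at the end of the night, in 11075 genes at ZT0, 5315 at ZT2 and 3396 at ZT6. At ZT0, Pp3c6_520 had 58.5 ± 13.5 CPM in NDUFA5 KO (n = 4) and 0.382 ± 0.473 in COX11 KO (n = 5), and Pp3c3_37060 had 22.9 ± 12.7 CPM against 3 counts, a ratio of 241 (81.9 to 1170). Pp3c1_40420 was higher in COX11 KO (26.2 ± 34.1 against 0.139 ± 0.17 CPM; edgeR adjusted p = 0.00311), as was Pp3c19_16160 (2.06 ± 2.03 CPM against 0 counts, at least 13.7-fold). At ZT2, Pp3c23_1050 was higher in COX11 KO (1.99 ± 0.3 against 0.145 ± 0.324 CPM, n = 5 each) and Pp3c9_23030 lower (0.182 ± 0.13 against 25.5 ± 26.7). Pp3c12_16420 had 0.726 ± 0.358 CPM in COX11 KO against 1 count, a ratio of 21.1 (3.43 to 866). Pp3c19_19150 had 0 counts in COX11 KO against 2.57 ± 3.65 CPM, at least 28.9-fold lower, but its call rested on the 2 line 48 libraries, without which the log2 fold change was -2.63 and the edgeR adjusted p 0.391. At ZT6, Pp3c5_12290 (37.5 ± 4.09 against 4.56 ± 0.975 CPM, n = 5 each) and Pp3c5_12030 (30.2 ± 12.2 against 4.93 ± 2.78) were higher in COX11 KO. Pp3c10_22850 (1.55 ± 0.797 against 177 ± 176) and Pp3c7_6750 (2 counts against 10.8 ± 14.4 CPM, a ratio of NDUFA5 KO to COX11 KO of 159, 43.8 to 1320) were lower. Of the genes called, 52.6%, 47.1% and 53.9% were higher in COX11 KO at the 3 times. With library totals only the share was 75.5% at ZT0 and 63% at ZT2, and the median log2 fold change of all genes at ZT0 moved from 0.092 to 0.48.

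In WT, 9182 genes differed between ZT0 and ZT2 (4610 higher, 4572 lower later) and 10484 between ZT0 and ZT6 (5253 higher, 5231 lower later), and 6335 differed between ZT2 and ZT6. Pp3c24_9770 rose from 3 counts over 6 libraries at ZT0 to 12.8 ± 7.37 CPM at ZT2 (n = 4) and 13 ± 7.23 at ZT6 (n = 8), each a ratio of 129 (43.7 to 628 and 43.8 to 627). Pp3c20_3400 was at 9.01 ± 5.82 CPM at ZT2 against 0.13 ± 0.16 at ZT0, and Pp3c15_21480 at 15 ± 13.9 CPM at ZT6 against 0.138 ± 0.174. Pp3c13_2400 fell from 57.3 ± 83.3 CPM at ZT0 to 0.2 ± 0.294 at ZT2 and 0.267 ± 0.335 at ZT6, and Pp3c4_2680 from 32.5 ± 37.5 to 0.23 ± 0.352 at ZT2. Pp3c3_37540 fell in steps, from 114 ± 29 CPM at ZT0 to 49.5 ± 7.73 at ZT2 and 1.46 ± 1.15 at ZT6. Between ZT2 and ZT6, Pp3c15_4410 rose from 0.443 ± 0.0726 to 16.4 ± 4.62 CPM and Pp3c9_7820 from 5.37 ± 2.22 to 105 ± 40, while Pp3c3_9610 fell from 8.4 ± 5.16 CPM to 1 count, a ratio of 326 (57.8 to 13000). For the named genes of the WT time contrasts, adjusted p in edgeR's quasi-likelihood test was at most 7.22e-05. The 6 WT libraries at ZT0 all carry code letter Z and the 4 at ZT2 letter A, so time and letter coincide between them. With the letter as a covariate, estimated from the other groups, 7636 genes were called between ZT0 and ZT2.

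By the interaction test, the knockout effects differed between times, in more genes for NDUFA5 KO than for COX11 KO. For COX11 KO the effect differed from that at ZT0 in 1554 genes at ZT2 and 4917 at ZT6, and for NDUFA5 KO in 6040 and 8534. Pp3c4_24420 had 425 ± 82.6 CPM in NDUFA5 KO at ZT0 (n = 4) against 3.6 ± 1.85 in WT (n = 6), but 17.1 ± 3.04 against 9.78 ± 2.52 at ZT2, an interaction of -6.07 in log2 with a standard error of 0.394. Pp3c2_27000 had 130 ± 72.4 CPM in NDUFA5 KO against 1.62 ± 1.04 at ZT0, and 1.04 ± 0.717 against 1.24 ± 0.852 at ZT6. Pp3c1_31210 went the other way, with 0.163 ± 0.11 CPM in NDUFA5 KO against 2.83 ± 2.79 at ZT0 and 58.4 ± 57.6 against 2.1 ± 1.14 at ZT2. Pp3c4_26050 had 0 counts in NDUFA5 KO at ZT0 (1.87 ± 1.57 CPM in WT) and 4.48 ± 1.45 CPM against 3.69 ± 1.14 at ZT6. In COX11 KO, Pp3c25_14630 was at 165 ± 40.1 CPM at ZT0 and 7.51 ± 2.3 at ZT6, where WT had 16 ± 31.9. Pp3c24_18690 was at 2.02 ± 1.36 CPM in COX11 KO against 123 ± 67.7 in WT at ZT0, and 72.1 ± 60.1 against 186 ± 77.7 at ZT2. Pp3c15_2630 was at 0.566 ± 0.382 CPM in COX11 KO at ZT0 (2 counts over 6 WT libraries) and 2.52 ± 0.721 against 3.81 ± 0.69 at ZT2. Without COX11 KO 150-2 at ZT6, the interactions of Pp3c9_3710 and Pp3c12_13360 fell from 4.99 and 4.69 to 1.63 and 1.29, with edgeR adjusted p = 0.731 and 0.747. With library totals only, 73.5% and 75.5% of the NDUFA5 KO interactions at ZT2 and ZT6 were positive, against 50% and 50.1% with TMM, and the median over all genes moved from 0.069 and 0.074 to 0.33 and 0.44.

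Genes that differed between ZT0 and ZT2 in WT changed in the same direction, on median, in both knockouts. Over 120 choices of part of the WT libraries, 1828 to 2380 genes were higher at ZT2 and 1470 to 1993 lower. Their median log2 change in the remaining WT libraries was 1.34 (range over choices 1.07 to 1.5) and -1.23 (-1.36 to -0.99). In COX11 KO the same genes changed by 0.98 (0.89 to 1.05) and -1.01 (-1.09 to -0.84), and in NDUFA5 KO by 1.4 (1.27 to 1.53) and -1 (-1.12 to -0.7). These ranges come from overlapping choices and are not a test between genotypes.

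**Figure D3:**
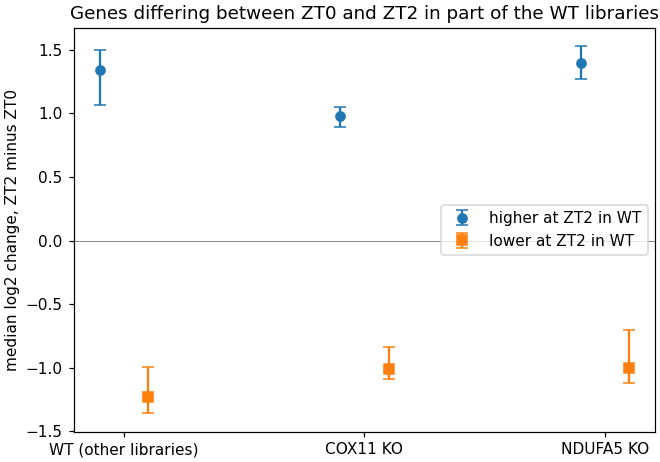
Median log2 change from ZT0 to ZT2 (y axis) of genes found higher (circles) or lower (squares) at ZT2 in part of the WT libraries, measured in the other WT libraries and in each knockout. Bars span the lowest and highest of 120 choices, and the changes of 1.34, 0.98 and 1.4 are all above 0.

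Lines of the same genotype differed in fewer genes than genotypes did. Between COX11 KO lines 150 (8 libraries) and 152 (7 libraries), edgeR called 0 genes, with 510 at an unadjusted p under 0.05, and DESeq2 called 1. Between NDUFA5 KO lines 46 (8 libraries) and 48 (6 libraries), 560 genes were called, 318 of them higher in line 46 (56.8%, and 44.2% with library totals only). That number depended on single libraries. Of these, 46-3 at ZT6 is of uncertain line: 265 genes were called without it, and 67 with it taken as line 48. Leaving out 48-1 at ZT2 gave 110, 48-1 at ZT6 145, 48-2 at ZT0 154, 46-2 at ZT0 236, 48-1 at ZT0 264 and 46-3 at ZT2 345. It fell to 125 without the genes of the prefixes Pp3c2, Pp3c25 and Pp3c27.

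Genes of the ID prefix Pp3c2 were on median higher in all knockout libraries. The median over 1143 genes was 0.92 ± 0.0266 above WT on the log2 scale in COX11 KO (SD, n = 15), 0.72 ± 0.232 in NDUFA5 KO (n = 14) and 0.0072 ± 0.0198 in WT (n = 18), and it exceeded the highest WT library in 15 of 15 and 14 of 14. Permutation p was 1e-05 for each, the smallest 100000 resamples can give, and 3e-05 after adjustment over 54 tests. The libraries of each knockout come from 2 lines, so these p-values cover the spread between libraries and not that between lines. The means of the other 26 prefixes differed from WT by -0.063 to -0.0019 in COX11 KO and by -0.088 to 0.065 in NDUFA5 KO. Of these, 24 and 21 also passed adjusted p < 0.05, at those sizes. Of the Pp3c2 genes, 79.2%, 75.2% and 75.2% were called higher in COX11 KO at ZT0, ZT2 and ZT6, and 62.3%, 57.2% and 75.2% in NDUFA5 KO. Without the genes of prefixes Pp3c2, Pp3c25 and Pp3c27, 6204, 4279 and 6819 genes were called for COX11 KO against WT and 10127, 7052 and 5877 for NDUFA5 KO.

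Line 48 differed from the rest in these genes. The Pp3c2 median was 0.85 ± 0.068 in line 46 (n = 8) and 0.54 ± 0.262 in line 48 (n = 6), whose libraries varied. It was 0.761 and 0.774 in the line 48 libraries at ZT0 and 0.453 and 0.751 at ZT6, and 0.783 to 0.789 in line 46 at ZT2. The line 48 libraries at ZT2 had Pp3c2 medians of 0.153 and 0.344, and were also high in Pp3c25 genes (0.809 and 0.49) and Pp3c27 genes (0.783 and 0.544). In the other 45 libraries the highest medians of those prefixes were 0.0453 and 0.11. Without these line 48 libraries, 8180 genes were called for NDUFA5 KO against WT at ZT2, in place of 8113, but the remaining 3 knockout libraries all carry code letter Z and the 4 WT libraries letter A, so genotype and letter coincide there.

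**Figure D4:**
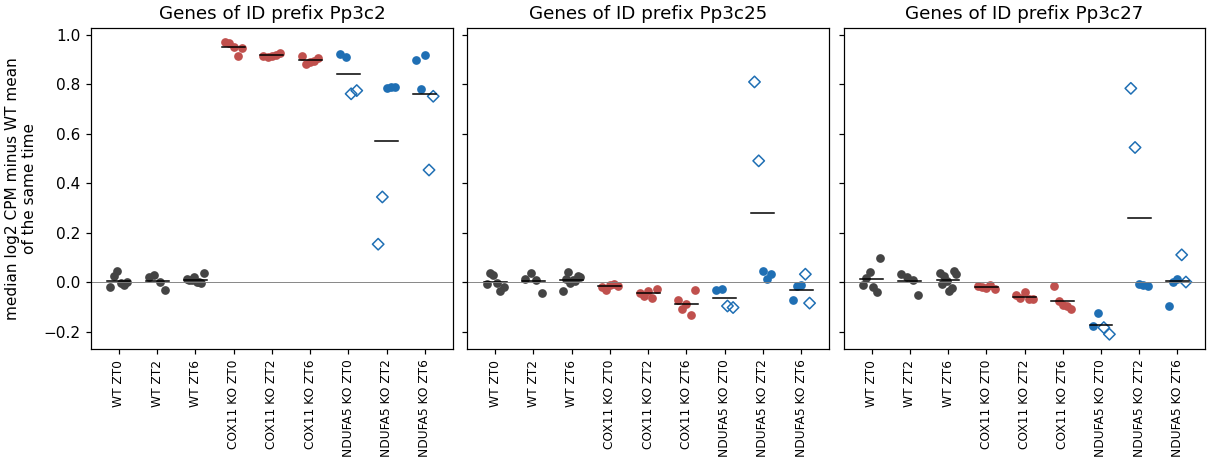
Median over genes of 3 ID prefixes of log2 CPM minus the WT mean of the same time (y axis), 1 point per library, by group, with group means as lines and line 48 as open diamonds. The Pp3c2 median is higher in all knockout libraries than in any WT library, and those of Pp3c25 and Pp3c27 are raised in the line 48 libraries at ZT2.

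In log2 CPM, 67 genes were lower and 70 higher in every library of both knockouts than in any WT library, and 55 of the higher ones were of the ID prefix Pp3c2. If all libraries were exchangeable, chance would separate them so in a share of 2.19e-13 of genes per direction. No overlap with either other genotype was found for 2 genes low in COX11 KO, and for 2 low and 1 high in NDUFA5 KO. Genes with a gap of more than 1 in log2 CPM were singled out after their values were seen. Pp3c16_1230 was the only such gene low in COX11 KO alone, with 0.308 ± 0.223 CPM (0 to 5 counts, n = 15) against 12.4 ± 2.67 in WT (n = 18) and 16.6 ± 3.91 in NDUFA5 KO (n = 14). Pp3c5_12290 was the only such gene low in NDUFA5 KO alone, with 4.88 ± 1.96 CPM (11 to 65 counts) against 36.5 ± 7.99 in WT and 34.3 ± 7.46 in COX11 KO. Their log2 fold changes against WT were -5.29, -5.81 and -4.83 for Pp3c16_1230 in COX11 KO and -2.73, -3.26 and -2.74 for Pp3c5_12290 in NDUFA5 KO at ZT0, ZT2 and ZT6, each with a standard error of at most 0.302. Pp3c5_12290 was also lower in COX11 KO at ZT0, by a log2 fold change of -0.78 with a standard error of 0.163 (edgeR adjusted p = 0.00015), and Pp3c16_1230 was higher in NDUFA5 KO at ZT0 by 0.69 (edgeR adjusted p = 0.00105). The names of these genes are not given in the files. With a gap of more than 1, another 15 genes were low and 2 high in all libraries of both knockouts. The most abundant of the low ones was Pp3c8_7680, with 8160 ± 2180 CPM in WT, 356 ± 153 in COX11 KO and 498 ± 275 in NDUFA5 KO. Pp3c14_22870 had 5490 ± 2710 CPM in WT, 313 ± 159 in COX11 KO and 297 ± 177 in NDUFA5 KO. The high ones were Pp3c21_13440 (0.0524 ± 0.0878 CPM in WT, 4.28 ± 1.36 in COX11 KO, 4.54 ± 2.15 in NDUFA5 KO) and Pp3c2_12100 (0.507 ± 0.343, 9.05 ± 2.11 and 6.81 ± 3.86).

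**Figure D5:**
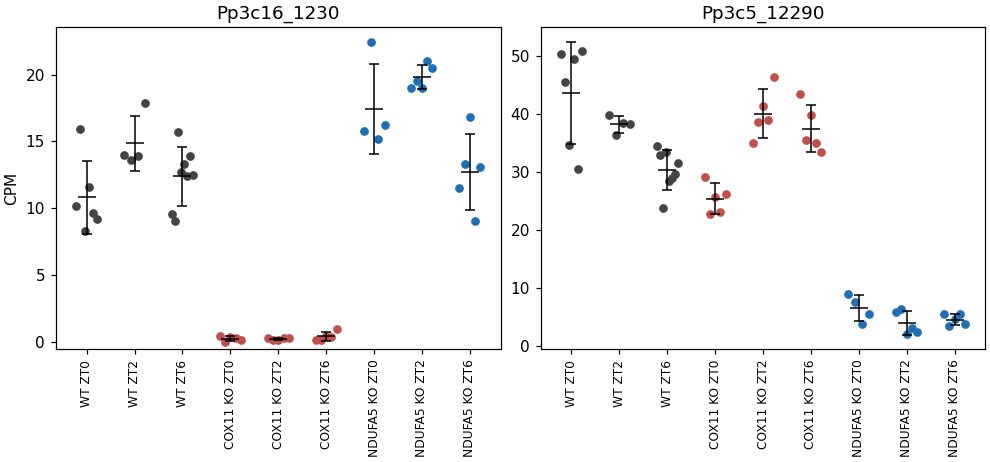
CPM (y axis) of Pp3c16_1230 and Pp3c5_12290 in each library by group, with the group mean and SD. Pp3c16_1230 has 0 to 5 counts in the 15 COX11 KO libraries, and Pp3c5_12290 has 11 to 65 counts in the 14 NDUFA5 KO libraries.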

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

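The tests of the end-of-night pattern in NDUFA5 KO were chosen after that pattern had been seen, with what each would show written down before its value was known, and the reading of the night-state test was changed to take in its spread after its value was known. The splits of the libraries were planned. Libraries with values far from the rest of their group were found by a rule that chance nominally meets in about 1 in 20 groups. In 74 groups, 11 were found. The nominal rate does not hold where all other libraries of a group lack counts of a gene, since any count then meets the rule. Several of the 11 were of this kind (below), so their number does not show an excess over chance.

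The NDUFA5 KO effect was larger at ZT0 than later, with 5883 genes changed at least 2-fold against 2776 for COX11 KO at that time, and it differed from ZT0 in 6040 genes at ZT2 and 8534 at ZT6. A few abundant genes were argued against as the whole cause, since 5923 genes changed at least 2-fold without the 50 genes of highest counts. Deeper sequencing of 1 library was too, since 5879 did so after that library was thinned. A stronger night state of WT was tested as the correlation across genes of the NDUFA5 KO effect at ZT0 with the WT difference between ZT0 and ZT2, and gave 0.0069 on average over WT choices (-0.0933 to 0.145), where the highest passes the bound of 0.1 set beforehand but none reaches 0.3. A dependence of plants without NDUFA5 on light may remain as a hypothesis, but no test here separates it from culture conditions of the ZT0 boxes, which were wrapped in foil.

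The knockout and time contrasts were each tested with 30 splits of the compared libraries, in a fit of those libraries alone. No other split called as many genes as the real one. That argues against chance where the other splits stayed well below, but does not exclude it. With 30 splits, 1 of 30 is the smallest share possible, and it was not adjusted over contrasts. For COX11 KO against WT, the real count and the highest of the other splits were 5011 and 3228 at ZT0, 6553 and 3128 at ZT2, and 8003 and 0 at ZT6. For NDUFA5 KO they were 9342 and 0, 7135 and 0, and 6883 and 977. Between the knockouts they were 10451 and 5005, 4528 and 0, and 3335 and 0. For the WT times they were 7508 and 410 (ZT2 and ZT0), 9109 and 461 (ZT6 and ZT0), and 6845 and 0 (ZT6 and ZT2). For the COX11 KO interactions they were 1339 and 0 at ZT2 and 4470 and 0 at ZT6. For the NDUFA5 KO interactions they were 4643 and 4127, and 7870 and 7397, with a median of 0 over the other splits in both. Labels were shuffled within each time, so a split can keep much of the real grouping at a given time. Whether the highest other split did so was not examined. It came close to the real count, and the splits leave chance open there. In each of these, 1 of 30 splits, the real one, reached the real count. Between lines 150 and 152 the real count was 0 and the highest other 58, so that 30 of 30 splits were necessarily as large and the splits decide nothing there. Chance cannot be excluded for lines 46 and 48, where the real count was 316 and the highest other 2419, with 3 of 30 as large, and a split that calls several times the real count points to a structure of the samples, which was not identified.

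The knockouts differed from each other in 11075 genes at ZT0, 5315 at ZT2 and 3396 at ZT6, by a test of the difference. The COX11 KO effect differed from that at ZT0 in 1554 genes at ZT2 and 4917 at ZT6. Between lines 46 and 48, 560 genes were called, a count for which chance was not excluded and which moved to between 67 and 855 with other settings.

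The library NDUFA5 KO 46-2 at ZT0 held 10.3 M counts (5.03 to 5.83 in the others of its group), and NDUFA5 KO 48-1 at ZT6 held 4.78 M (5.66 to 5.93). WT library 4 at ZT0 had log2 CPM of 0.29 for Pp3c11_18420 (5.14 to 7.05 in the others) and 0.0075 for Pp3c16_3130 (4.65 to 5.83). In groups otherwise at or near 0 counts, single libraries held 1 or 2 counts: Pp3c21_13440 had a log2 CPM of -0.96 in WT 3 at ZT2, Pp3c24_12720 -0.81 in WT 5 at ZT0, and Pp3c7_12530 -0.16 in WT 7 at ZT6 (-1.48 to -0.88 in the others). In knockouts, Pp3c11_18420 and Pp3c10_18650 both had -0.86 in COX11 KO 150-2 at ZT6, Pp3c11_18420 had -0.91 in NDUFA5 KO 48-2 at ZT2 and Pp3c1_34890 -0.93 in NDUFA5 KO 46-3 at ZT6.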

How the results depend on the processing

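Leaving out the prefixes Pp3c2, Pp3c25 and Pp3c27, library totals only, leaving out line 48 at ZT2, leaving out abundant genes and thinning were chosen after the data had been examined. Of 437 alternative values of 18 counts of called genes, 423 lay within 1.5 times the count reported and 14 did not, all of them between lines. Between lines 46 and 48 the count was 265 with the library of conflicting line left out, 67 with its line taken from the characteristics, 125 without the prefixes, 855 with DESeq2, and 110 to 717 with each library left out in turn. Between lines 150 and 152 it was 1 with DESeq2 and 0 to 1 with each library left out. The cause was not tested. The comparison of lines 46 and 48 without both line 48 libraries at ZT2 was not run, because line 48 then has no library at that time. With the title number as a replicate block, 6857, 5293 and 7033 genes were called for COX11 KO against WT and 10926, 7905 and 5772 for NDUFA5 KO, and no count moved by over 1.5 times. Libraries sharing a number deviated together no more than others. The mean correlation was -0.00962 over 231 pairs (47 of them over 0.1), against 0.00311 over 745 other pairs (164 over 0.1). Of 47 libraries, 12 correlated best with their own number. No sign of pairing by number was seen, but this check cannot exclude it. The correlation of the knockout effects was 0.597, 0.742 and 0.765 at ZT0, ZT2 and ZT6 without the prefixes, but genes higher in both knockouts fell to 1073, 1019 and 1445, from 1755, 1667 and 2268. With separate WT libraries the correlation was 0.547 and 0.534, 0.668 and 0.664, and 0.725 and 0.723, and at ZT2 the genes higher in both fell to 925 and 924 and those lower in both to 1406 and 1360, from 2161. The other counts of genes higher or lower in both stayed within 1.5 times. With separate WT libraries, genes called in opposite directions were 800 and 1062 at ZT0 (1226 with shared WT libraries). They were 39 and 59 at ZT2 (118) and 55 and 61 at ZT6 (104). The named genes of the contrasts of each knockout with WT and of the WT times kept their calls under all alternatives in which they could be tested. Settings in which a gene was filtered out or had no adjusted p are not counted, here or below. Calls were lost for Pp3c19_19150 between the knockouts and for 6 interactions: Pp3c13_4270 in 14 of 24 settings (edgeR adjusted p 0.0117 to 0.103, log2 fold change 4.39 to 4.97), Pp3c1_40420 in 8 of 33 (8.89e-05 to 0.0765, -10.9 to -6.15), Pp3c9_3710 in 6 (0.00611 to 0.731, 1.63 to 5.5), Pp3c12_13360 in 4 (0.00447 to 0.747, 1.29 to 5.07), Pp3c24_3650 in 2 (8.35e-05 to 0.225, -7.07 to -4.99, the highest p with the replicate block) and Pp3c13_5530 without WT 4 at ZT2 (0.0807, -2.37). None reversed. Depth limits genes at 0 to 3 counts, whose folds are bounds or wide ratios.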

Other observations

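The tests of the Pp3c2 and line 48 patterns below were chosen after the patterns had been seen.

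WT library 4 at ZT0 was low in genes that were low in both knockouts, but lay among WT in its Pp3c2 median and in Pp3c16_1230 and Pp3c5_12290. It stood apart from the other WT libraries at ZT0 in genes with counts, 19113 against 19663 to 20110. Its score on the second principal component was -58.0, against -101.3 to -72.5 in those libraries. Over 147 genes lower by more than 3 in log2 in both knockouts, its median deviation from the other WT libraries was -2.68 (143 genes below their mean), whereas in the other 17 WT libraries it lay between -0.94 and 1.09 and the knockouts had a median of -3.88. For each library the genes were chosen from the knockouts and the other WT libraries of its time, without that library, so their number differs between libraries. Its Pp3c2 median was -0.0034 (0.153 in the lowest knockout library), and it held 11.6 CPM of Pp3c16_1230 and 49.4 CPM of Pp3c5_12290 (8.34 to 15.9 and 30.5 to 50.9 in the other WT libraries at ZT0). This comparison was made after library 4 had been seen to stand apart.

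The raised Pp3c2 genes had a median of 0.92 in COX11 KO, or 1.89-fold, with medians of 0.84 to 0.98 over 10 blocks in ID order. A factor per library is argued against as the cause there, since it would move all prefixes alike, whereas the Pp3c2 median lay at least 0.86 above the highest other prefix in each of the 15 COX11 KO libraries, a gap seen with the pattern itself that no such factor changes. Reads split between genes, if splitting leaves fractional counts, are argued against too, since the 1056 Pp3c2 genes with whole counts had 0.93. In NDUFA5 KO the blocks had medians of 0.655 to 0.856, and the gap to the highest other prefix ran from -0.656 to 0.888, lowest in the line 48 library 48-1 at ZT2, where Pp3c25 genes were raised. An extra copy of a chromosome could give the COX11 KO values, as a hypothesis, if the prefix stands for a chromosome, which is not stated. Whether such a copy came with the transformation, with the loss of respiration or otherwise was not tested.

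The line 48 libraries at ZT2 had raised Pp3c25 and Pp3c27 genes and a lower Pp3c2 shift. Code letter A is argued against, since the other 7 knockout libraries with that letter had Pp3c25 medians of at most -0.032. None of the other 45 libraries exceeded 0.045. This does not decide on a swap within the series, since after an exchange the raised values would still lie in these libraries alone. Both held 5.8 and 6.39 CPM of Pp3c5_12290, against at least 22.7 in every WT and COX11 KO library. Their first-component scores were -10.55 and -8.022, against at least 130.4 in NDUFA5 KO at ZT0 and at most -40.93 at ZT6. These values argue against exchange with those groups, though the gene was singled out with these libraries included. Exchange with line 46 at ZT2 stays open. A mixture of cells with and without extra chromosome copies could give the mean Pp3c2 median of 0.25 at ZT2, but cannot be told apart from other causes, because values of whole cultures do not separate a mixture from another origin. The line 48 library 48-1 at ZT6 also had a low Pp3c2 median (0.453), with Pp3c25 and Pp3c27 medians of 0.0317 and 0.11. A swap with a sample from outside the series was not tested.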
